A study of Mus musculus with 142 samples.

How the data were processed

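The data are gene counts of 142 RNA sequencing libraries from 26 BALB/c mice bearing EMT6 tumours: 114 of blood labelled PBMC and 28 of tumour fine-needle aspirates. Per the labels, treatment began at a tumour volume of 100 mm3 with 200 µg of antibody followed by 100 µg weekly, RNA was extracted with the Maxwell LEV simplyRNA kit, and libraries were depleted of ribosomal RNA with NEBNext reagents. The processing notes of the submitters name cutadapt 2.10, FastQC 0.11.9, STAR 2.7.8a, featureCounts 2.0.2 and the genome build GRCm38.p6. The strand and multimapping settings of the counting step are not given there, so reads in overlapping genes and in paralogs may be shared or lost. The deposited values are counts per gene: 2 tables of whole numbers, with 40983 genes in 60 libraries (cohort 1, blood alone) and 41206 genes in 82 libraries (cohort 2, blood and tumour). The 39439 genes in both were used for blood fits that hold both cohorts. All columns were mapped to samples, with 0 libraries left unmapped. Each cohort has its own table, so cohort and batch of processing coincide.

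Library totals ran from 8239709 to 28724542 counts in blood, with a median of 18470000, and had a median of 23660000 in tumours. Each library within a group was compared with the others for repeated counts: of 163 pairs 0 were identical, the lowest chi-square per degree of freedom was 11.5, and the highest Pearson r of log2(count + 1) between any 2 libraries was 0.987. Groups, days, mice and cohorts were taken from the sample titles and labels. Mice without a library on a day were absent from that comparison. Libraries with fewer than 20000 detected genes (8) and the 11 libraries whose title ends in R (from 2 mice) were kept, and were left out in alternatives.

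Comparisons were made in edgeR 4.0.16 (R 4.3.3) with TMM normalization, filterByExpr and quasi-likelihood F tests, on the blood libraries of the day or pair of days compared with all arms in one fit, with cohort as a covariate. The day 28 fit held cohort 1 and the day 35 fit the cohort 1 responders of all days. All 28 tumour libraries were fitted together by arm and day. The 3 classes of treated mice had equal weight in comparisons of the antibodies. A gene was called at a Benjamini-Hochberg adjusted p of at most 0.05 over all genes tested. The SE of a log2 fold change is its absolute value divided by the square root of F. The comparisons, tests, lists and rule for named genes were set before the data were examined. Exceptions, settled after values were seen, are the 2 comparisons of day 21 with day 14, the order in which lists were filled with named genes, the exact permutation tests of list scores, the tests of cohort, haemoglobin and cell type as explanations, the splits with mouse as a replicate block, the test of interferon-stimulated genes against blood in the aspirate, and 5 of the alternatives.

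Gene lists (29) were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data, adjusted over all lists of a comparison. A list needed at least 5 tested members. Members past the threshold were also counted with adjustment over the list alone. Skin keratinocytes and milk proteins never had 5 tested members. Over the 22 planned comparisons the submandibular gland list was tested in 8 and called in 0 (medians -0.34 to 0.14). Macrophages were called up in 1 and down in 1 (medians -0.31 to 0.46), dendritic cells up in 0 and down in 1 (-1.58 to 0.78), epithelium up in 1 and down in 2 (-0.74 to 1.13), adipocytes up in 1 and down in 5 of 17 (-2.17 to 0.53), skeletal muscle up in 3 and down in 1 (-0.99 to 0.82), and with an estimated correlation each of these in 0.

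Named genes were, for each comparison: up to 4 called members of each list that was called or had at least 3 called members, with the largest absolute change; the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1, with the same sign in both cohorts; and 7 preset genes (Cd274, Pdcd1, Pdcd1lg2, Cd8a, Gzmb, Ifng, Isg15) whether called or not. At most 30 genes were named per comparison, and lists were filled in the order of list-test p. The 10 and 10 left out unnamed loci, pseudogenes and variable segments of antigen receptors; in comparisons with fewer than 5 calls all were named. Called variable segments numbered 36 up and 0 down between responder and intrinsic resistant blood at day 21, 96 and 0 at day 28, and 0 and 73 in anti-PD-L1 blood from day 7 to day 14.

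Libraries of the same mouse on different days are repeated measures by the labels, so mouse pairs the samples of comparisons between days. How far it did so was checked with the Pearson r of log2 values, after removing group means, between libraries of the same mouse: the median was 0.0514 for blood days 1 and 7, -0.00379 for days 7 and 14, 0.0641 for days 14 and 21 and 0.0513 for tumours of days 7 and 14. The fit without mouse was set beforehand for all comparisons and the fit with mouse as a replicate block as an alternative, given beside a result where it changes a call or moves a count by over 1.5 times. The other alternatives set beforehand were DESeq2 1.42.0 with its own size factors, DESeq2 size factors in edgeR, no count filter, haemoglobin genes left out, each cohort alone, libraries ending in R left out, and leaving out each mouse in turn. Added after the data were seen were rRNA-related genes left out, the log2 share of rRNA-related counts as a covariate, and libraries of few detected genes left out. For anti-PD-L1 tumours of day 14 against day 7 the last pair were also each joined with mouse as a replicate block.

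The fits were tested on simulated data with the design and dispersion of these libraries, with about 200 genes changed. The changed genes had a mean log2 CPM of at least 1. Each gene was drawn independently, without correlation between genes or effects of mouse or library quality. The shares and false calls hold for such data alone. In the real day 14 tumours of responder and intrinsic resistant mice, splits other than the real one called up to 1668 genes. In the blood comparison of responder with intrinsic resistant mice at day 14, 49.3%, 77.6% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 6 false calls among 158. In the same tumour comparison the shares were 0%, 11.9% and 68.2%, with 2 false calls among 55, and for the difference of the tumour change from day 7 to day 14 between these classes they were 0%, 4.48% and 36.4%, with 0 among 27. For anti-PD-L1 tumours of day 14 against day 7 they were 16.4%, 71.6% and 95.5%, with 4 among 127.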

Results

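RNA sequencing counts were collected from blood and tumours of the same BALB/c mice over the course of EMT6 tumours, a mouse mammary carcinoma line. Blood was taken from the submandibular vein and is labelled PBMC, and tumours were sampled by fine-needle aspirate. The 26 mice received a mouse IgG1 control antibody (mIgG1, 7 mice) or an antibody against PD-L1 (19 mice), the ligand of the T cell inhibitory receptor PD-1. The labels divide the 19 treated mice into responders (7), intrinsic resistant (6) and acquired resistant (6). The criterion of these classes is not in the labels used. There were 142 libraries, 114 of blood and 28 of tumour. Blood day 1 preceded tumour injection and had 5 acquired resistant, 6 intrinsic resistant, 6 responder and 7 mIgG1 libraries. Day 7 preceded treatment, and days 14 and 21 were 7 and 14 days after its start. Each of these 3 days had 6, 6, 7 and 7 libraries in the same order. Day 28 had 3 libraries of each treated class, and day 35 had 3 responder libraries. Tumours of days 7 and 14 came from 3 acquired resistant, 3 intrinsic resistant, 4 responder and 4 mIgG1 mice. The mice formed 2 cohorts, of 12 and 14, and tumours came from cohort 2 alone. Library totals ran from 8239709 to 28724542 counts.

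The first principal component of blood held 11.5% of the variance, and cohort accounted for a share of 0.627 of it. Haemoglobin genes took 2.93% of counts (SD 4.14, n = 60) in cohort 1 blood and 0.0181% (SD 0.0377, n = 54) in cohort 2. In the tumours the first component held 45.3%, with a share of 0.69 for day and a Pearson r of -0.84 with the number of detected genes. The locus Gm26917, which overlaps ribosomal RNA sequence, took 12.3% of blood counts and 29.4% of tumour counts. Of the 142 libraries, 4 of blood and 4 of day 14 tumours had fewer than 20000 detected genes. Below, a value after a gene name is its log2 fold change ± SE. All calls are edgeR adjusted p at most 0.05 over all tested genes. Of each gene list, the measured members called over all genes are counted first, and those called with p adjusted over the list alone follow in brackets. The 2 p values of a list test are those with the preset and with an estimated correlation between genes. Genes of the same family with shared sequence, such as Hba-a1 and Hba-a2 or Ifit3 and Ifit3b, are not independent measurements.

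**Figure D1:**
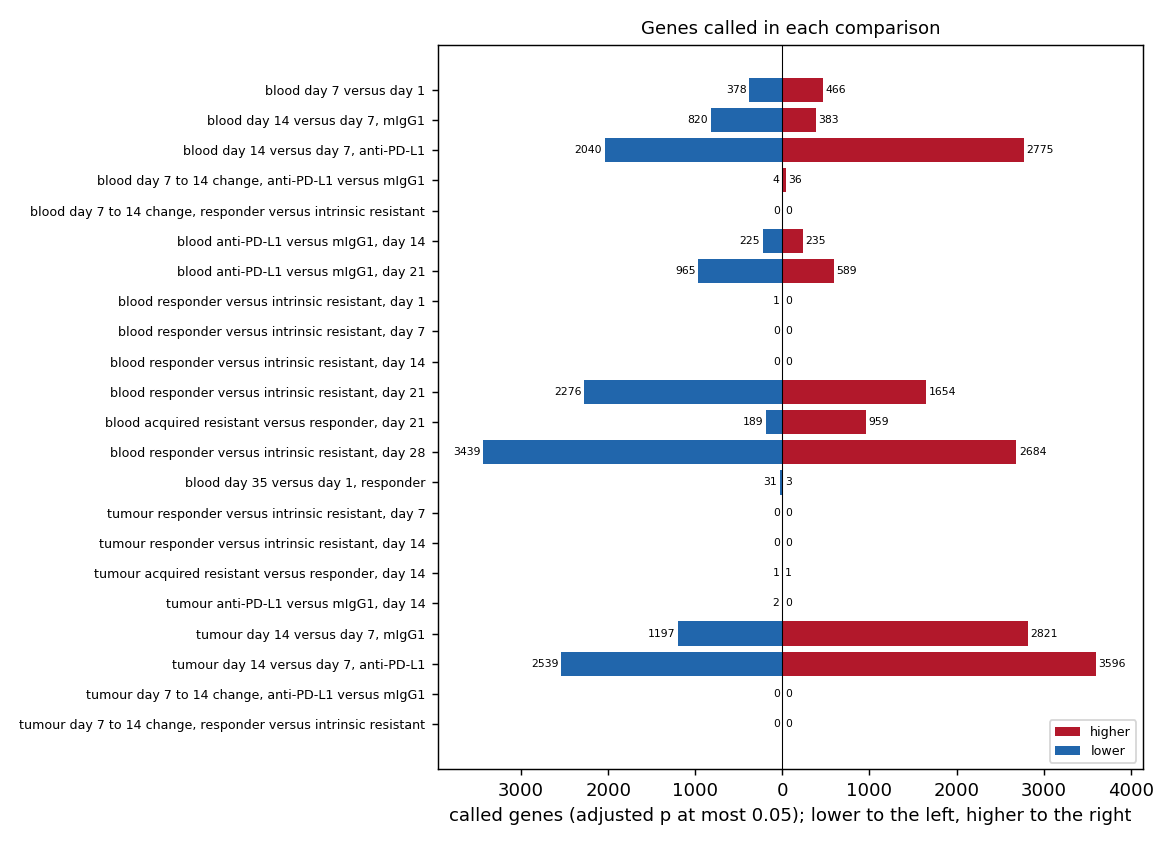
Number of genes called higher (right) or lower (left) in each of the 22 comparisons, at adjusted p at most 0.05. Responder and intrinsic resistant blood differed by 0 genes at days 7 and 14, 3930 at day 21 and 6123 at day 28.

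What changed in blood once a tumour was present was asked by comparing day 7 with day 1, both before treatment (26 and 24 libraries). No mice without a tumour were sampled at day 7. The tumour therefore cannot be told apart from elapsed time, repeated bleeding or a batch by day. Some T cell and interferon genes were called upward. Among T cell genes, 14 of 22 rose (20 over the list alone, 6 with mouse as a replicate block), median 0.61 (cohort 1 1.30, cohort 2 0.09), among them Tcf7 (0.84 ± 0.21), a transcription factor of naive T cells, Bcl11b (0.83 ± 0.20) and Cd3g (0.82 ± 0.19), a chain of the T cell receptor complex. The list test gave adjusted p = 1.53e-23, and adjusted p = 0.220 with an estimated correlation; in cohort 2 alone neither it (adjusted p = 0.217) nor the interferon gamma list (0.0851) was called. Of interferon-stimulated genes, 9 of 30 rose (16 over the list alone), median 0.28 (cohort 1 0.36, cohort 2 0.17), among them Ifi44 (0.77 ± 0.15), Zbp1 (0.55 ± 0.10) and Mx1 (0.50 ± 0.12), at adjusted p = 6.72e-12, and adjusted p = 0.221 with an estimated correlation. Among interferon gamma response and MHC class I genes, 5 of 26 rose (11 over the list alone), at adjusted p = 0.220 with an estimated correlation; Nlrc5 (0.42 ± 0.09), a transactivator of MHC class I, was one. Among monocyte genes, 7 of 20 rose and 2 fell (11 up and 5 down over the list alone), at adjusted p = 0.225 with an estimated correlation. The risers included Ly6c2 (0.80 ± 0.11) and Ccr2 (0.67 ± 0.16), markers of classical monocytes, and Mafb (0.90 ± 0.22). Of plasma cell genes, 4 of 19 fell (5 over the list alone), at adjusted p = 0.225 with an estimated correlation. One was Jchain (-0.85 ± 0.21), the joining chain of secreted antibody. Of erythroid genes, 4 of 26 rose (17 over the list alone, 0 with mouse as a replicate block), at adjusted p = 0.551 with an estimated correlation, led by Hba-a1 (2.64 ± 0.62) and Hbb-bs (2.27 ± 0.59); the list was not called without libraries of few detected genes (adjusted p = 0.0797), and with DESeq2 Hbb-bs was -0.14. With mouse as a replicate block their adjusted p was 0.457 and 0.428. In all, 844 of 21198 genes were called, 466 up and 378 down. The cohorts gave different genes: alone they called 1147 and 215, and of 1143 genes called in cohort 1 and tested in both, 57.7% had the same sign in cohort 2 and 17 were called there in the same direction and 2 in the opposite one.

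In mIgG1 mice (7 libraries per day), day 14 was compared with day 7 to measure the course of blood without PD-L1 blockade. Of platelet genes, 12 of 17 fell (16 over the list alone, 2 with mouse as a replicate block), median -1.34 (cohort 1 -1.30, cohort 2 -1.41), including Itga2b (-1.55 ± 0.37), the platelet integrin alpha IIb (not called with mouse as a replicate block), at adjusted p = 2.12e-16, and adjusted p = 0.186 with an estimated correlation. Of endothelial genes, 6 of 10 fell (7 over the list alone), at adjusted p = 0.186 with an estimated correlation. They included Esam (-1.50 ± 0.33) and Kdr (-1.27 ± 0.28), and Vwf (-1.50 ± 0.38), which is also made by platelets. Among mature neutrophil genes, 8 of 19 rose (15 over the list alone, 4 with mouse as a replicate block), median 0.67 (cohort 1 0.94, cohort 2 0.54), including Wfdc17 (2.53 ± 0.58), Wfdc21 (2.27 ± 0.51) and S100a8 (1.34 ± 0.32), a calcium-binding alarmin subunit, at adjusted p = 0.216 with an estimated correlation. Of neutrophil granule genes, 3 of 15 rose (4 over the list alone), among them Ngp (1.93 ± 0.49) and Ltf (1.79 ± 0.52), at adjusted p = 0.257 with an estimated correlation. Of interferon-stimulated genes, 9 of 30 rose and 1 fell (17 up and 1 down over the list alone), including Oasl2 (1.39 ± 0.31) and Rtp4 (0.96 ± 0.18) upward and Ifit2 (-1.14 ± 0.28) downward, at adjusted p = 0.257 with an estimated correlation. Of erythroid genes, 3 of 26 rose (3 up and 1 down over the list alone), led by Hba-a2 (6.03 ± 1.47) and Hba-a1 (5.06 ± 1.40), median 0.87 (cohort 1 4.18, cohort 2 -0.06), at adjusted p = 0.656 with an estimated correlation; cohort 1 alone called 1 of 26 (22 over the list alone). Gzmb (1.00 ± 0.27), a protease of cytotoxic cells, and Isg15 (1.14 ± 0.35) rose. With mouse as a replicate block the adjusted p of these 2 genes and Vwf was 0.0732, 0.0568 and 0.0564. In all, 1203 of 20443 genes were called, 383 up and 820 down. Mouse as a replicate block gave 697, and cohorts 1 and 2 alone called 246 and 672. Without the libraries of few detected genes the count was 1823. With 1 mouse left out the count was 436 without M404, 768 without M406, 776 without M17968, 778 without M17958, 791 without M17953.

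Over the same interval in anti-PD-L1 mice (19 libraries per day) interferon genes rose, in 28 of 30 and 24 of 26 members of 2 lists. Of interferon-stimulated genes, 28 of 30 rose (28 over the list alone), median 1.15 (cohort 1 1.32, cohort 2 1.07), at adjusted p = 1.74e-71, and adjusted p = 1.79e-04 with an estimated correlation. The largest rises were Oasl2 (2.79 ± 0.20), Ifit1 (1.96 ± 0.15) and Ifit3 (1.84 ± 0.15), all antiviral effectors. Of interferon gamma response and MHC class I genes, 24 of 26 rose (24 over the list alone), median 0.93 (cohort 1 1.21, cohort 2 0.71), among them the GTPases Gbp2 (2.38 ± 0.20) and Gbp5 (1.91 ± 0.17), at adjusted p = 1.28e-46, and adjusted p = 3.01e-04 with an estimated correlation. Transcripts of the antibody's own target rose: Cd274 (1.35 ± 0.11), which encodes PD-L1 (ENSMUSG00000016496.7, chromosome 19, 29367455 to 29388095, GRCm38.p6). Gzmb (1.56 ± 0.16) and Isg15 (1.67 ± 0.21) rose, and Pdcd1lg2 (-0.87 ± 0.16), which encodes PD-L2, and Cd8a (-0.51 ± 0.14) fell. Among T cell genes, 19 of 22 fell (20 over the list alone), median -0.53 (cohort 1 -0.39, cohort 2 -0.67), including Cd8b1 (-0.83 ± 0.17) and Trbc2 (-0.83 ± 0.16), at adjusted p = 0.352 with an estimated correlation. Of B cell genes, 14 of 21 fell (18 over the list alone, 8 with mouse as a replicate block), at adjusted p = 0.588 with an estimated correlation, including Blk (-0.50 ± 0.12) and Fcmr (-0.56 ± 0.16). Of plasma cell genes, 2 of 19 rose and 8 fell (3 up and 11 down over the list alone), at adjusted p = 0.431 with an estimated correlation. Of platelet genes, 7 of 17 fell (12 over the list alone, 3 with mouse as a replicate block), median -0.57 (cohort 1 -1.26, cohort 2 -0.03), at adjusted p = 0.692 with an estimated correlation; the list was not called in cohort 2 alone (adjusted p = 0.581). Among mature neutrophil genes, 15 of 19 rose (16 over the list alone), median 0.68 (cohort 1 0.69, cohort 2 0.65), at adjusted p = 0.266 with an estimated correlation, including S100a9 (1.14 ± 0.19). Of granule genes, 10 of 15 rose (11 over the list alone), at adjusted p = 0.0961 with an estimated correlation, including Ltf (2.31 ± 0.32) and Ly6g (1.91 ± 0.29). In all, 4815 of 20443 genes were called, 2775 up and 2040 down. The cohorts alone called 1978 and 5276. Over genes tested in both, 699 were called in both with the same sign and 54 with opposite signs, and 73.9% of cohort 1 calls had the same sign in cohort 2. The B cell and plasma cell lists were not called in cohort 1 alone (adjusted p = 0.101 and 0.209).

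Whether the change differed between the antibodies was tested directly as anti-PD-L1 change minus mIgG1 change. Both interferon lists were called upward, with few of their genes called singly. Of interferon-stimulated genes, 5 of 30 had a more positive change under anti-PD-L1 (21 over the list alone, 1 with mouse as a replicate block), median difference 0.70 (cohort 1 0.77, cohort 2 0.68), at adjusted p = 4.24e-25, and adjusted p = 0.0472 with an estimated correlation. Of interferon gamma response and MHC class I genes, 4 of 26 had a more positive change (18 over the list alone, 2 with mouse as a replicate block), median difference 0.73 (cohort 1 0.95, cohort 2 0.51), at adjusted p = 6.19e-25, and adjusted p = 0.0302 with an estimated correlation. Cd274 (1.04 ± 0.21) itself rose more (1.08 in cohort 1 and 0.98 in cohort 2): its level went from 36.5 CPM (SD 4.88, n = 7) to 45.3 (SD 8.46) in mIgG1 blood, against 74.7 to 89.9 CPM in the 3 treated classes at day 14. Of the 7 preset genes it alone was called. The others, with Gzmb and Isg15 among them, ran from -0.72 to 1.45 (edgeR adjusted p 0.253 or more). At day 14 Isg15 stood at 65.7 CPM in mIgG1 blood and at 67.4 to 80.2 CPM in the treated classes. The largest differences included Ifit3 (1.53 ± 0.28) (ENSMUSG00000074896.3, chromosome 19, 34583531 to 34588731), Ifit2 (1.42 ± 0.33), Igtp (1.14 ± 0.20) (ENSMUSG00000078853.8, chromosome 11, 58199556 to 58207591), Irgm1 (1.13 ± 0.24), Irf1 (1.02 ± 0.24) and Stat1 (0.95 ± 0.18), the last pair being interferon-response transcription factors. Others were Ifi205 (1.77 ± 0.35), Ifi47 (1.33 ± 0.25), Olfr56 (1.84 ± 0.36), Herc6 (1.14 ± 0.24), Ifit3b (1.24 ± 0.29), Myof (1.31 ± 0.29) and Ly6a (1.18 ± 0.28). Ifit2 was called downward in mIgG1 blood over these days, so part of its difference comes from that fall. Olfr56 overlaps Ifi47 on the annotation, as Igtp overlaps Irgm2. The 4 genes that fell relative to mIgG1 included Fabp4 (-2.35 ± 0.42), a fatty acid carrier of adipocytes and macrophages, Cd300e (-1.85 ± 0.29) (ENSMUSG00000048498.7, chromosome 11, 115051917 to 115062177), a receptor of non-classical monocytes, and Slc12a2 (-0.96 ± 0.19). Of T cell genes, 0 of 22 passed (0 over the list alone), median -0.41 (cohort 1 0.15, cohort 2 -0.86), at adjusted p = 2.89e-08, and adjusted p = 0.595 with an estimated correlation. In all, 40 of 20443 genes were called, 36 up and 4 down. On cohort 1 alone edgeR called 0 and on cohort 2 alone 490. In both cohorts together 2148 genes had an unadjusted p under 0.05 and DESeq2 called 178. Without libraries whose title ends in R 128 were called, 99 up and 29 down, and with the rRNA-related share as a covariate 23, 20 up and 3 down. With mouse as a replicate block 16 were called, 12 up and 4 down, and the adjusted p was 0.0605 for Cd274, 0.0537 for Stat1, 0.134 for Irf1, 0.121 for Ifit2, 0.0678 for Ifit3b, 0.105 for Herc6, 0.0586 for Olfr56, 0.103 for Myof and 0.135 for Ly6a. Counts with 1 mouse left out were 12 without M405, 13 without M17958 or M404, 18 without M17968, 21 without M387, 22 without M399 or M397, 23 without M398, 25 without M17951 or M389, 67 without M17961, 74 without M17962, 85 without M17969, 87 without M17970, 91 without M17956, 100 without M402.

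**Figure D2:**
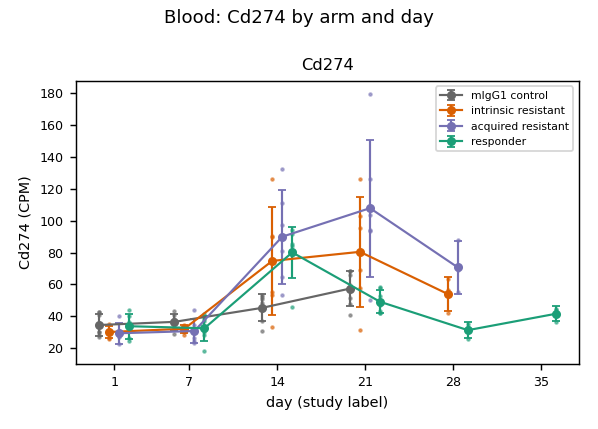
Cd274 in blood (CPM) by study day; small points are mice, larger points and bars the mean ± SD of each arm, offset around the day. At day 21 the responder mean was 49.1 CPM, the mIgG1 mean 57.4, the intrinsic resistant mean 80.4 and the acquired resistant mean 108.

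At day 14, anti-PD-L1 blood (19 libraries) was also compared with mIgG1 blood (7) directly. Interferon gamma response and MHC class I genes were higher: 15 of 26 were higher (23 over the list alone), median 0.77 (cohort 1 0.67, cohort 2 0.72), including Gbp5 (1.25 ± 0.29) and Irgm1 (1.16 ± 0.20), at adjusted p = 9.11e-28, and adjusted p = 0.0399 with an estimated correlation. Of interferon-stimulated genes, 18 of 30 were higher and 1 was lower (27 up and 1 down over the list alone), median 0.64 (cohort 1 0.66, cohort 2 0.72), at adjusted p = 0.0882 with an estimated correlation; Phf11d (1.24 ± 0.25) was higher and Rsad2 (-1.45 ± 0.32) lower. Erythroid genes were lower: 14 of 26 were lower (24 over the list alone), median -1.56 (cohort 1 -1.69, cohort 2 -1.40), including Hba-a1 (-4.18 ± 1.02) and Trim10 (-2.24 ± 0.44), at adjusted p = 2.62e-32, and adjusted p = 0.0399 with an estimated correlation. Among cytotoxic and NK genes, 2 of 22 were higher (11 over the list alone), Gzmb (1.04 ± 0.28) and Klrg1 (0.94 ± 0.22), at adjusted p = 0.524 with an estimated correlation. Single monocyte genes moved apart: Cd300e (-1.96 ± 0.18) and Cd36 (-1.85 ± 0.32) were lower while Fcgr1 (1.13 ± 0.25) and Ly6c2 (0.87 ± 0.23) were higher. Fabp4 (-1.92 ± 0.29) was lower and Cd274 (0.86 ± 0.19) higher. In all, 460 of 19269 genes were called, 235 up and 225 down. Cohort 1 alone called 1 and cohort 2 alone 344. The count was 125 with the rRNA-related share as a covariate, 199 without libraries of few detected genes and 296 without the count filter. DESeq2 called 862. Leaving out 1 mouse gave 188 without M17968, 199 without M402, 269 without M404, 286 without M406, 750 without M391.

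At day 21 (19 and 7 libraries) cytotoxic genes were called upward and neutrophil and monocyte genes downward under anti-PD-L1. Of cytotoxic and NK genes, 18 of 23 were higher (19 over the list alone), median 0.99 (cohort 1 0.55, cohort 2 1.43), including Ifng (1.71 ± 0.44), the gene of interferon gamma, Gzma (1.18 ± 0.21), Klrg1 (1.18 ± 0.23) and Gzmb (0.97 ± 0.21), at adjusted p = 1.04e-27, and adjusted p = 0.0430 with an estimated correlation. Among mature neutrophil genes, 15 of 19 were lower (19 over the list alone), median -0.63 (cohort 1 -0.58, cohort 2 -0.69), including Wfdc17 (-1.56 ± 0.31) and Lrg1 (-1.22 ± 0.21), at adjusted p = 4.10e-25, and adjusted p = 0.0430 with an estimated correlation. The treated classes differed in that list: its mean log2 CPM was 6.15 (SD 0.26, n = 7) in responders, 7.21 (SD 0.42, n = 6) in acquired resistant and 7.63 (SD 0.23, n = 6) in intrinsic resistant mice, against 7.73 (SD 0.38, n = 7) in mIgG1 mice. Of monocyte genes, 8 of 20 were lower (3 up and 9 down over the list alone), median -0.31 (cohort 1 -0.34, cohort 2 -0.17), at adjusted p = 0.0740 with an estimated correlation. Among them were Cd300e (-2.31 ± 0.22), Ace (-1.10 ± 0.15), Treml4 (-0.95 ± 0.11) and Nr4a1 (-0.81 ± 0.11), all markers of non-classical monocytes. Of interferon gamma response and MHC class I genes, 11 of 26 were higher (17 over the list alone), median 0.52 (cohort 1 0.48, cohort 2 0.59), including Iigp1 (2.04 ± 0.38) and Tgtp2 (1.18 ± 0.16), at adjusted p = 0.0766 with an estimated correlation. Of hypoxia and glycolysis genes, 10 of 21 were lower (13 over the list alone), at adjusted p = 0.0766 with an estimated correlation, including Egln3 (-0.75 ± 0.15) and Slc2a1 (-0.62 ± 0.15). Of immediate early and heat shock genes, 4 of 12 were lower (6 over the list alone), at adjusted p = 0.0766 with an estimated correlation, including Fos (-0.55 ± 0.12) and Junb (-0.53 ± 0.10). Pdcd1lg2 (-0.81 ± 0.24) was lower; Cd274 (0.40 ± 0.16) did not pass. In all, 1554 of 19229 genes were called, 589 up and 965 down. Cohort 1 alone called 18 and cohort 2 alone 1167. The count was 476 with the rRNA-related share as a covariate. With 1 mouse left out the count was 832 without M406, 963 without M17968, 1014 without M404.

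Whether later response classes already differed before or early in treatment was asked by comparing responder with intrinsic resistant blood on each day. On day 1 (6 and 6 libraries), before tumours, 1 of 20250 genes was called, Gm48488 (-6.87 ± 1.09), an unnamed locus overlapping Gas1, lower in responders. It was tested in cohort 2 alone of the 2 cohorts and not called there. Over both cohorts 550 genes had an unadjusted p under 0.05 and DESeq2 called 0. Counts with 1 mouse left out were 0 without M17956 or M17969 or M387 or M397 or M398 or M17962 or M17973 or M389 or M393 or M401. On day 7 (7 and 6), edgeR and DESeq2 each called 0 of 19526 genes, with 1096 at an unadjusted p under 0.05.

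On day 14 (7 and 6 libraries), after 7 days of treatment, edgeR called 0 of 19269 genes, with 2464 at an unadjusted p under 0.05; DESeq2 called 66, of which 62 were lower in responders. Of mature neutrophil genes, 0 of 19 passed (12 down over the list alone), median -0.62 (cohort 1 -0.71, cohort 2 -0.57), at adjusted p = 2.01e-12, and adjusted p = 0.505 with an estimated correlation. Among cytotoxic and NK genes, 0 of 22 passed (0 over the list alone), median 0.53 (cohort 1 0.85, cohort 2 0.29), at adjusted p = 1.69e-08, and adjusted p = 0.534 with an estimated correlation. Cd274 gave 0.14 ± 0.23, at 80.1 CPM (SD 16.0, n = 7) in responders and 74.7 CPM (SD 33.7, n = 6) in intrinsic resistant mice, with opposite signs in the cohorts (0.86 and -0.46). The count was 3 without mouse M17962 and 2 without the count filter. The change from day 7 to day 14 was also compared between these classes. There edgeR and DESeq2 each called 0 of 20443 genes, with 1071 at an unadjusted p under 0.05, and so did edgeR with mouse as a replicate block.

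By day 21 responder (7) and intrinsic resistant (6) blood differed in neutrophil, lymphocyte and interferon genes. Mature neutrophil genes were lower in responders: 19 of 19 were lower (19 over the list alone), median -1.40 (cohort 1 -1.43, cohort 2 -1.30), at adjusted p = 2.38e-30, and adjusted p = 0.0356 with an estimated correlation. Among the largest differences were Wfdc17 (-3.01 ± 0.46) (ENSMUSG00000069792.5, chromosome 11, 83703991 to 83706268), Lrg1 (-2.39 ± 0.30) (ENSMUSG00000037095.8, chromosome 17, 56119678 to 56122001), a secreted glycoprotein of neutrophil granules, and Stfa2l1 (-1.73 ± 0.21). Of neutrophil granule genes, 1 of 14 was higher and 7 were lower (1 up and 9 down over the list alone), median -1.04 (cohort 1 -0.95, cohort 2 -1.28), at adjusted p = 0.0960 with an estimated correlation. They included Ly6g (-1.80 ± 0.31), Lcn2 (-1.74 ± 0.24) and Mmp8 (-1.45 ± 0.19). Of B cell genes, 20 of 21 were higher (20 over the list alone), median 0.81 (cohort 1 0.60, cohort 2 0.93), including Fcrla (0.97 ± 0.25) and Blk (0.88 ± 0.18), at adjusted p = 0.285 with an estimated correlation. Among cytotoxic and NK genes, 15 of 23 were higher (17 over the list alone), median 0.81 (cohort 1 0.99, cohort 2 0.68), at adjusted p = 0.285 with an estimated correlation. Examples were Tbx21 (1.07 ± 0.28), the T-bet transcription factor, and S1pr5 (1.05 ± 0.17). Of MHC class II genes, 8 of 10 were higher (10 over the list alone), at adjusted p = 0.305 with an estimated correlation. Among interferon-stimulated genes, 23 of 30 were lower (25 over the list alone), median -0.83 (cohort 1 -0.66, cohort 2 -1.14), at adjusted p = 0.182 with an estimated correlation. Examples were Oas3 (-1.35 ± 0.15) and Isg15 (-1.27 ± 0.25). Of interferon gamma response and MHC class I genes, 10 of 26 were lower (11 over the list alone), median -0.31 (cohort 1 0.09, cohort 2 -0.71), at adjusted p = 0.448 with an estimated correlation. Of inflammatory cytokine genes, 6 of 21 were lower (7 over the list alone), at adjusted p = 0.182 with an estimated correlation. Of monocyte genes, 2 of 20 were higher and 7 were lower (2 up and 8 down over the list alone), at adjusted p = 0.305 with an estimated correlation. Cd274 (-0.65 ± 0.20) was lower (-0.08 in cohort 1 and -1.19 in cohort 2).

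In all, 3930 of 19229 genes were called at day 21 between responder and intrinsic resistant blood, 1654 up and 2276 down. The cohorts alone called 1102 (149 up) and 1764 (485 up). Over genes tested in both, 699 were called in both with the same sign and 0 with opposite signs, and 98.3% of cohort 1 calls had the same sign in cohort 2. The rRNA-related share of counts was 15.1% (SD 4.10, n = 7) in responders and 12.3% (SD 3.93, n = 6) in intrinsic resistant mice, and with it as a covariate 964 genes were called, 130 up and 834 down.

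**Figure D3:**
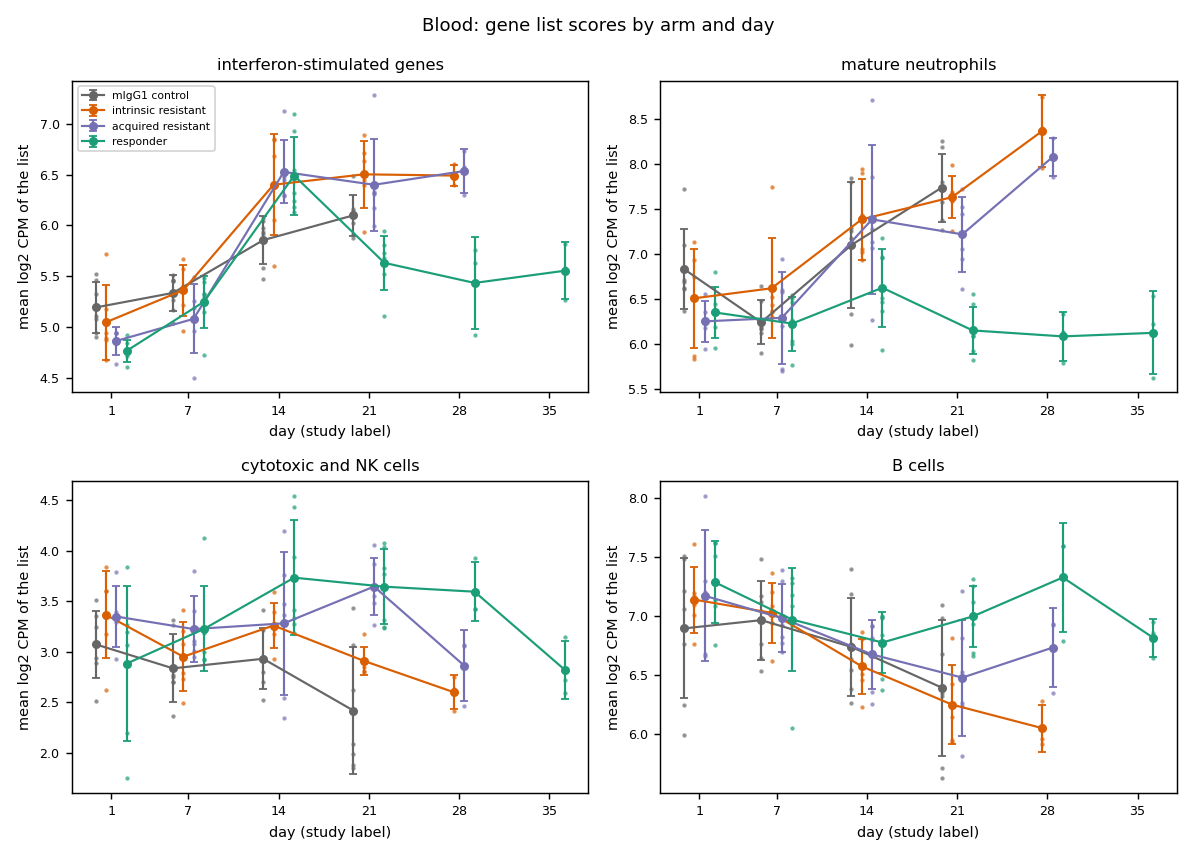
Mean log2 CPM over the genes of 4 lists in blood by study day; small points are mice, larger points and bars the mean ± SD of each arm, offset around the day. The responder mean of the mature neutrophil list was 6.62 at day 14 and 6.15 at day 21, against 7.38 and 7.63 in intrinsic resistant mice.

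Whether the difference between responder and intrinsic resistant blood grew from day 14 to day 21 was tested by a comparison chosen after the data were seen. Of interferon-stimulated genes, 0 of 30 passed (26 down over the list alone), median -0.99 (cohort 1 -1.18, cohort 2 -0.72), at adjusted p = 1.47e-35, and adjusted p = 0.0503 with an estimated correlation (0.0219 with mouse as a replicate block). Of mature neutrophil genes, 0 of 19 passed (2 down over the list alone), median -0.63 (cohort 1 -0.83, cohort 2 -0.62), at adjusted p = 8.20e-10, and adjusted p = 0.262 with an estimated correlation. edgeR called 0 of 20331 genes, with 1520 at an unadjusted p under 0.05, DESeq2 called 15, and edgeR with mouse as a replicate block called 37, 1 up and 36 down.

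The same test for anti-PD-L1 against mIgG1 blood, also chosen after the data were seen, called 0 genes in edgeR and 502 in DESeq2, with 3625 at an unadjusted p under 0.05. Cohort 2 alone called 203. Leaving out 1 mouse gave 1 without M17962, 239 without M17968, 650 without M17953. Among T cell genes, 0 of 22 passed (21 up over the list alone), median 0.78 (cohort 1 0.17, cohort 2 1.20), at adjusted p = 2.41e-15, and adjusted p = 0.216 with an estimated correlation.

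Acquired resistant mice were compared with responders at day 21 (6 and 7 libraries). Neutrophil and interferon genes were higher in acquired resistant blood. Of mature neutrophil genes, 16 of 19 were higher (18 over the list alone), median 1.02 (cohort 1 1.10, cohort 2 0.84), including Wfdc17 (2.71 ± 0.46), Lrg1 (1.94 ± 0.30) and S100a8 (1.43 ± 0.22), at adjusted p = 1.65e-30, and adjusted p = 0.0353 with an estimated correlation. Of granule genes, 6 of 14 were higher (9 up and 1 down over the list alone), median 0.96 (cohort 1 1.06, cohort 2 1.02), including Ly6g (1.70 ± 0.31) and Camp (1.45 ± 0.38), at adjusted p = 1.30e-08, and adjusted p = 0.0400 with an estimated correlation. Of interferon gamma response and MHC class I genes, 15 of 26 were higher (18 over the list alone), median 0.69 (cohort 1 0.23, cohort 2 1.22), including Gbp2 (2.02 ± 0.29), Gbp5 (1.72 ± 0.33) and the chemokine Cxcl10 (1.54 ± 0.44), at adjusted p = 3.41e-23, and adjusted p = 0.0458 with an estimated correlation. Of interferon-stimulated genes, 22 of 30 were higher (24 over the list alone), median 0.82 (cohort 1 0.56, cohort 2 1.08), including Oas3 (1.16 ± 0.15) and Isg15 (1.18 ± 0.25), at adjusted p = 0.0520 with an estimated correlation. Cd274 (1.10 ± 0.20) was higher (0.65 in cohort 1 and 1.52 in cohort 2), as was Acod1 (2.19 ± 0.30), which makes itaconate in activated myeloid cells. Of B cell genes, 5 of 21 were lower (14 over the list alone), at adjusted p = 0.185 with an estimated correlation, including Ebf1 (-0.68 ± 0.16) and Pax5 (-0.62 ± 0.17). Of eosinophil, basophil and mast cell genes, 5 of 15 were lower (5 over the list alone), at adjusted p = 0.164 with an estimated correlation. In all, 1148 of 19229 genes were called, 959 up and 189 down. The cohorts alone called 103 and 262. With 1 mouse left out the count was 611 without M386.

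At day 28 responder and intrinsic resistant blood had 3 libraries each, all from cohort 1. Of mature neutrophil genes, 19 of 19 were lower (19 over the list alone), median -2.21, including Wfdc17 (-4.36 ± 0.68), Lrg1 (-3.51 ± 0.33) and Ifitm1 (-3.26 ± 0.38), at adjusted p = 0.173 with an estimated correlation. Of granule genes, 1 of 15 was higher and 13 were lower (1 up and 13 down over the list alone), at adjusted p = 0.171 with an estimated correlation, including Prtn3 (-4.03 ± 0.36) and Ly6g (-3.21 ± 0.28). Among B cell genes, 21 of 21 were higher (21 over the list alone), median 1.28, at adjusted p = 0.352 with an estimated correlation, including Fcrla (1.58 ± 0.31) and Cd79a (1.44 ± 0.28). Of T cell genes, 20 of 22 were higher (20 over the list alone), at adjusted p = 0.352 with an estimated correlation, including Ccr7 (1.24 ± 0.18) and Cd28 (0.97 ± 0.18). Of cytotoxic and NK genes, 17 of 21 were higher (19 over the list alone), at adjusted p = 0.352 with an estimated correlation, including Ncr1 (1.16 ± 0.21). Of interferon-stimulated genes, 21 of 30 were lower (24 over the list alone), at adjusted p = 0.352 with an estimated correlation, including Oas2 (-1.84 ± 0.24) and Isg15 (-1.71 ± 0.21). Of inflammatory cytokine genes, 12 of 20 were lower (12 over the list alone), at adjusted p = 0.272 with an estimated correlation. Cd274 (-0.84 ± 0.20) was lower and Pdcd1lg2 (1.02 ± 0.27) higher. In all, 6123 of 18178 genes were called, 2684 up and 3439 down. The rRNA-related share of counts was 24.5% (SD 0.674, n = 3) in responders and 21.1% (SD 7.14, n = 3) in intrinsic resistant mice, and the haemoglobin share was 2.04% (SD 1.40) and 6.30% (SD 2.82).

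Whether responder blood returned to its state before tumour injection was asked by comparing day 35 with day 1 in the 3 responders of cohort 1. Called genes included Arhgef25 (-4.60 ± 0.75), Plxnb3 (-2.21 ± 0.33), the clock gene Ciart (-2.29 ± 0.36), the cytokine gene Tnf (-1.83 ± 0.35) and the replication genes Cdc6 (-1.96 ± 0.30) and Chek1 (-1.60 ± 0.28) downward and H1f3 (1.86 ± 0.35) and Sntb1 (1.04 ± 0.20) upward. Of interferon gamma response and MHC class I genes, 0 of 26 passed (15 up over the list alone), median 0.78, at adjusted p = 4.83e-15, and adjusted p = 0.278 with an estimated correlation. Among T cell genes, 0 of 22 passed (0 over the list alone), median 0.94, at adjusted p = 4.83e-15, and adjusted p = 0.332 with an estimated correlation. Pdcd1 (2.74 ± 0.70) did not pass in edgeR but did in DESeq2. In all, 34 of 19600 genes were called, 3 up and 31 down, and DESeq2 called 329. With DESeq2 size factors the split was 10 up and 34 down, without haemoglobin genes 7 and 31, and without rRNA-related genes 13 and 36. The count was 4 with the rRNA-related share as a covariate, 122 without libraries of few detected genes and 64 without the count filter. Counts with 1 mouse left out were 0 without M17973, 7 without M17962, 17 without M17951.

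In the tumours, day 14 was compared with day 7 within each arm. In mIgG1 mice (4 aspirates per day), interferon, neutrophil and inflammatory genes rose. Of interferon-stimulated genes, 30 of 30 rose (30 over the list alone), median 4.29, including Rsad2 (7.43 ± 0.76) and Ifit1 (6.32 ± 0.76), at adjusted p = 2.17e-39, and adjusted p = 0.0699 with an estimated correlation. Of mature neutrophil genes, 19 of 19 rose (19 over the list alone), median 4.67, including Asprv1 (6.15 ± 0.69) and Il1r2 (5.67 ± 0.70), at adjusted p = 3.73e-25, and adjusted p = 0.0660 with an estimated correlation. With mouse as a replicate block the estimated-correlation test of that list gave adjusted p = 0.00413. Of inflammatory cytokine genes, 22 of 26 rose (22 over the list alone), including Il1a (6.86 ± 0.76), Il1b (6.37 ± 0.85) and the neutrophil chemoattractant Cxcl2 (6.21 ± 0.81), at adjusted p = 0.0557 with an estimated correlation. With mouse as a replicate block it was 0.00311. Among cytotoxic and NK genes, 19 of 23 rose (20 over the list alone), at adjusted p = 0.264 with an estimated correlation. Of T cell genes, 12 of 22 rose (19 over the list alone), at adjusted p = 0.309 with an estimated correlation. Of fibroblast and extracellular matrix genes, 17 of 23 fell (1 up and 18 down over the list alone), at adjusted p = 0.195 with an estimated correlation, including Col5a2 (-2.71 ± 0.49) and Fbn1 (-2.54 ± 0.45). Cd274 (6.09 ± 0.81) rose, from 15.9 CPM (SD 8.14, n = 4) to 1085 (SD 926, n = 4), as did Gzmb (5.44 ± 1.11) and Cd8a (3.40 ± 0.79). In all, 4018 of 21404 genes were called, 2821 up and 1197 down. Of the 4 day 14 libraries, those of M402 and M406 had fewer than 20000 detected genes (19967 and 18068), and without them 3288 were called, 2741 up and 547 down. Leaving out 1 mouse gave 1839 without M405, 1959 without M406.

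In anti-PD-L1 tumours (10 aspirates per day) interferon, neutrophil and lymphocyte genes rose over the same days. Of interferon-stimulated genes, 30 of 30 rose (30 over the list alone), median 3.13, including Rsad2 (5.74 ± 0.46) and Ifit3 (4.88 ± 0.46), at adjusted p = 1.50e-43, and adjusted p = 0.0436 with an estimated correlation; with mouse as a replicate block the latter was 0.0779. Of mature neutrophil genes, 19 of 19 rose (19 over the list alone), median 4.21, including Hdc (5.28 ± 0.53), S100a9 (4.79 ± 0.43) and Retnlg (4.76 ± 0.60), at adjusted p = 2.50e-32, and adjusted p = 0.0208 with an estimated correlation. Of inflammatory cytokine genes, 21 of 26 rose (22 over the list alone), including Acod1 (5.79 ± 0.56) and Il1b (5.57 ± 0.53), at adjusted p = 3.33e-26, and adjusted p = 0.0208 with an estimated correlation. Among T cell genes, 19 of 22 rose (19 over the list alone), at adjusted p = 0.132 with an estimated correlation, including Cd8a (4.55 ± 0.52) and Itk (3.92 ± 0.61). Of cytotoxic and NK genes, 22 of 23 rose (22 over the list alone), at adjusted p = 0.132 with an estimated correlation, including Gzmb (5.28 ± 0.71) and Prf1 (4.70 ± 0.54), the pore-forming protein. Pdcd1 (3.94 ± 0.63), which encodes PD-1, and Cd274 (4.94 ± 0.49) rose. Of fibroblast and extracellular matrix genes, 1 of 23 rose and 17 fell (2 up and 18 down over the list alone), at adjusted p = 0.132 with an estimated correlation. Of endothelial genes, 1 of 16 rose and 13 fell (1 up and 13 down over the list alone), at adjusted p = 0.132 with an estimated correlation. Of cell cycle genes, 21 of 30 fell (25 over the list alone), at adjusted p = 0.337 with an estimated correlation. In all, 6135 of 21404 genes were called, 3596 up and 2539 down. Of the day 14 libraries those of M391 and M401 had fewer than 20000 detected genes.

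The tumour change from day 7 to day 14 was compared between the arms and between responder and intrinsic resistant mice. For anti-PD-L1 against mIgG1, edgeR and DESeq2 each called 0 of 21404 genes, with 548 at an unadjusted p under 0.05; Cd274 (-1.15 ± 0.78) and Cd8a (1.16 ± 0.91) did not pass. For responder against intrinsic resistant mice both called 0, with 505 at an unadjusted p under 0.05.

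**Figure D4:**
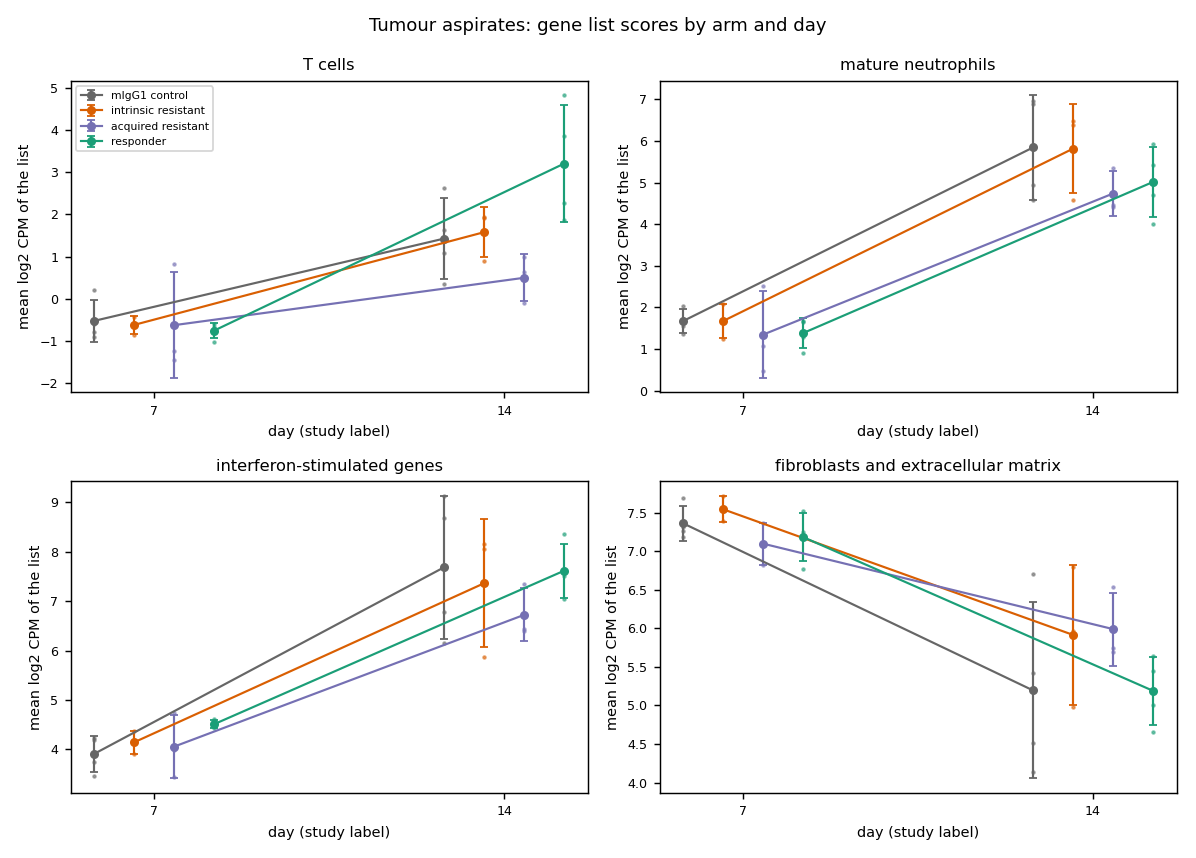
Mean log2 CPM over the genes of 4 lists in tumour aspirates of days 7 and 14; small points are mice, larger points and bars the mean ± SD of each arm, offset around the day. The mean of the T cell list at day 14 was 3.20 in responders, 1.58 in intrinsic resistant, 0.50 in acquired resistant and 1.43 in mIgG1 mice.

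Tumours of the response classes were compared on each day. On day 7, before treatment (4 responders, 3 intrinsic resistant), edgeR and DESeq2 each called 0 of 21404 genes, with 18 at an unadjusted p under 0.05. On day 14 edgeR called 0, with 1662 at an unadjusted p under 0.05, and DESeq2 called 27. Of T cell genes, 0 of 22 passed (13 up over the list alone), median 1.88, at adjusted p = 1.56e-16, and adjusted p = 0.322 with an estimated correlation. Of T cell activation and checkpoint genes, 0 of 14 passed (3 up over the list alone), median 1.46, at adjusted p = 0.322 with an estimated correlation. Cd8a (3.30 ± 0.81), the CD8 co-receptor, and Pdcd1 (3.08 ± 0.99) did not pass over all genes. Without the libraries of few detected genes, 2 of which were responder aspirates of day 14, the T cell median was 0.38 (adjusted p = 0.116) and the activation and checkpoint median 0.16 (0.248), so neither list was called, and the count of genes was 1.

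Day 14 tumours of acquired resistant mice (3) were compared with those of responders (4). The chemokine gene Ccl5 (-3.36 ± 0.57) (ENSMUSG00000035042.2, chromosome 11, 83525778 to 83530518) was lower and Papss1 (1.23 ± 0.20) (ENSMUSG00000028032.13, chromosome 3, 131564768 to 131643671), a sulphate donor synthase, was higher. The T cell list was called downward at the preset correlation: 0 of 22 passed (20 down over the list alone), median -3.28, at adjusted p = 3.71e-19, and adjusted p = 0.213 with an estimated correlation. Among cytotoxic and NK genes, 1 of 23 was lower (14 over the list alone), median -2.87, at adjusted p = 0.230 with an estimated correlation. Of activation and checkpoint genes, 0 of 14 passed (11 down over the list alone), at adjusted p = 0.213 with an estimated correlation. Of mitochondrially encoded genes, 0 of 12 passed (9 up over the list alone), median 1.62, at adjusted p = 0.252 with an estimated correlation. Without libraries of few detected genes these 4 medians were -1.61, -1.35, -0.94 (against -2.27) and 1.03, each still called at the preset correlation. Cd8a (-4.00 ± 0.84), Pdcd1 (-4.58 ± 1.08), Gzmb (-3.32 ± 1.10) and Ifng (-3.26 ± 1.27) did not pass over all genes in edgeR; all but Ifng did in DESeq2. The rRNA-related share of counts was 40.9% (SD 6.87, n = 3) in acquired resistant and 31.9% (SD 4.87, n = 4) in responder tumours. Those 2 genes of 21404 were the edgeR calls, with 3953 at an unadjusted p under 0.05, and DESeq2 called 1119, 308 up and 811 down. With DESeq2 size factors in edgeR 10 were called, 3 up and 7 down, and without the count filter 12. The count was 0 without libraries of few detected genes and 0 without libraries whose title ends in R. With 1 mouse left out the count was 0 without M386 or M399 or M391 or M401, 7 without M392, 113 without M389, 955 without M393. M391 and M401 were the responder aspirates with few detected genes. In edgeR Cd8a was called without M389 (-4.30, adjusted p = 0.0351) or M393 (-4.35, 0.014), and Pdcd1 without M393 (-4.96, 0.0185). Cd8a ran from 8.76 to 131.8 CPM over the 4 responder aspirates and from 1.82 to 3.70 CPM over the 3 acquired resistant ones. The count and these calls thus depend on which responder aspirates are held.

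Anti-PD-L1 (10) and mIgG1 (4) tumours were compared at day 14. The 2 called genes, Gm44005 (-4.56 ± 0.76) and Gm49209 (-6.13 ± 0.91), were lower under anti-PD-L1; both are unnamed loci, overlapping Mgll and P4htm. Cd274 (-0.92 ± 0.52), Isg15 (-0.94 ± 0.39) and Gzmb (0.17 ± 0.76) did not pass, Gzmb changing sign without libraries of few detected genes (-0.23), and 2195 of 21404 genes had an unadjusted p under 0.05. DESeq2 called 50, the count was 0 with the rRNA-related share as a covariate and 0 without libraries of few detected genes. Counts with 1 mouse left out were 0 without M386 or M392 or M399 or M405 or M406 or M397 or M398 or M393, 1 without M387, 4 without M404.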

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

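The following tests were chosen after their results were seen: the cohort tests of the neutrophil and interferon patterns, the haemoglobin test and the test of more neutrophils or monocytes. So were the tests of interferon-stimulated genes and of haemoglobin against blood in the aspirate. The tests of the rRNA-related share and of libraries with few detected genes were written before their results were seen, with alternatives that were added after the data were seen.

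Of 100 tests for a library far from the rest (5 readouts in 20 groups of 4 to 7 libraries), 8 found one; chance gives about 1 in 20, or 5. Cd274 was 46.0 CPM in responder M391 at blood day 14, against 78.8 to 93.9 in the other 6 libraries. The number of detected genes was 18233 in acquired resistant mouse M17955 at blood day 7 (others 24028 to 26440), 21315 in mIgG1 mouse M402 at blood day 1 (24465 to 26831), 19901 in the same mouse at blood day 14 (25634 to 26521) and 24658 in the day 7 tumour of mIgG1 mouse M406 (26450 to 26765). Gzmb was 21.4 CPM in mIgG1 mouse M17958 at blood day 21 (others 9.05 to 13.9). Isg15 was 130.5 CPM in acquired resistant mouse M386 at blood day 21 (43.4 to 63.4) and 68.3 CPM in mIgG1 mouse M404 at blood day 7 (15.1 to 32.3).

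The change from day 7 to day 14 in blood differed between anti-PD-L1 and mIgG1 mice by a test of the difference itself, in 40 genes. The named ones were Cd274 (1.04), Ifit3 (1.53), Ifit2 (1.42), Ifit3b (1.24), Herc6 (1.14), Igtp (1.14), Irgm1 (1.13), Irf1 (1.02), Stat1 (0.95), Fabp4 (-2.35), Cd300e (-1.85), Olfr56 (1.84), Ifi205 (1.77), Ifi47 (1.33), Myof (1.31), Ly6a (1.18) and Slc12a2 (-0.96). The same mice were sampled on both days, and with mouse as a replicate block 16 genes were called, 13 of them among the 40. Cd274, Ifit2, Ifit3b, Herc6, Irf1, Stat1, Olfr56, Myof and Ly6a were then not called (adjusted p 0.0537 to 0.135).

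Lower mature neutrophil genes in responder than intrinsic resistant blood at day 21 (median -1.40) were weighed against 2 technical explanations. A difference between cohorts would leave 1 of them without the difference, and the medians were -1.30 and -1.43 in the cohorts fitted alone. The rRNA-related share, higher in responders, left a median of -0.98 as a covariate, with the list still called, which argues against that share as the whole of the difference. The data hold no cell counts, so a lower share of neutrophils and a lower expression per neutrophil both stay open. The libraries are labelled PBMC, a preparation that normally removes mature neutrophils. A share of them would have to come from cells carried over or of low density, which was not tested. The response class itself stays open as an untested biological explanation. The labels used do not give the criterion of the classes, and the data hold no tumour volumes after the start of treatment. Response class and tumour size at day 21 therefore cannot be told apart.

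The larger rise of interferon-stimulated genes under anti-PD-L1 than under mIgG1 (median 0.70) was 0.675 and 0.767 in the cohorts alone, which argues against a difference between cohorts. Cohort 2 holds almost no haemoglobin counts, and its median of 0.675 argues against haemoglobin reads. More neutrophils or monocytes would raise their lists, whose medians were -0.10 and -0.15. Single monocyte genes moved apart between the antibodies at day 14 (Cd300e lower, Ly6c2 higher). The median of the monocyte list therefore cannot exclude a shift between kinds of monocyte, which stays open. Also open, as a hypothesis, is an effect of the antibody, which may act on blood cells or follow from changes in the tumour. The 7 mIgG1 mice carry the contrast.

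The rise of neutrophil and interferon genes in anti-PD-L1 tumours from day 7 to day 14 was weighed against blood in the aspirate. Scaled to S100a9 (tumour over blood 0.148), interferon-stimulated genes stood at a median of 11.9 times the level blood would bring, which argues against blood as their source. For the neutrophil genes it stays open. B cell genes stood at 0.0996, platelet genes at 0.0846 and eosinophil, basophil and mast cell genes at 0.246 of that level. Erythroid genes stood at 1.20, T cell genes at 1.59, plasma cell genes at 1.68 and the mature neutrophil list itself at 2.19. A ratio above 1 cannot show blood as the source, because cells of the tumour may hold the same transcripts (fibroblast and extracellular matrix genes stood at 31.4). The rule set beforehand weighed B cell genes alone and would have argued against blood. Erythroid genes were not part of it. Their ratio is taken over group means, in which single aspirates can weigh most. Alas2, an erythroid gene, was 964 CPM in the aspirate of M401, 262 CPM in that of M398 and at most 52.0 CPM in the others. Haemoglobin counts stood at 0.277 of the level blood would bring over the means, but at 0.0120 to 3.05 mouse by mouse, above 1 in 3 of 10. In cohort 2, which gave all tumours, they are few even in blood (145 CPM, against 1046 CPM of Alas2, an erythroid enzyme gene, and 5.95 and 141 CPM in the aspirates), so they decide nothing. The reference libraries are labelled PBMC, so blood in an aspirate may hold more neutrophils per B cell than they do. Without libraries of few detected genes the medians were 4.08 for neutrophil and 2.98 for interferon-stimulated genes, and with the rRNA-related share as a covariate 4.36 and 3.27, against 4.21 and 3.13 in all libraries. Joined with mouse as a replicate block these were 4.165 and 2.886, and 4.33 and 3.176. Tumour growth, the interval itself and the repeated aspirate stay open and untested; mIgG1 tumours were sampled on the same days.

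Other splits of the same mice or days tested whether chance can give as many called genes. In several comparisons only the real split gave its count, which makes chance less likely but does not exclude it. With 40 splits the share cannot fall below 1 of 40, and the shares were not adjusted over comparisons. This was so for blood day 7 against day 1 (1 of 40, real 844, highest other 112). It was so for day 14 against day 7 in mIgG1 (1 of 40, 1203, 1098) and anti-PD-L1 blood (1 of 40, 4815, 2675) and their difference (1 of 40, 40, 0). The same holds for anti-PD-L1 against mIgG1 blood at day 14 (1 of 100; 460, 2) and day 21 (1 of 100; 1554, 1), responder against intrinsic resistant at day 21 (1 of 100; 3930, 2436), acquired resistant against responder at day 21 (1 of 100; 1148, 311), and anti-PD-L1 tumours of day 14 against day 7 (1 of 100; 6135, 4705). For mIgG1 blood the margin is small. With any 1 of 5 mice left out the count was 436 to 791. Those fits hold fewer mice, so they cannot be set against the 1098 of a split of all 7. The same splits with mouse as a replicate block, chosen after the data were seen, gave a real count of 697 and a highest other of 50 there. They gave 654 and 11 for day 7 against day 1, 3712 and 1339 for anti-PD-L1 blood, 16 and 0 for the difference, and 5783 and 3832 for anti-PD-L1 tumours.

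Chance was not made less likely for responder against intrinsic resistant blood at day 1 (6 of 100, real 1, highest other 683). Nor was it in day 14 tumours for acquired resistant against responder (8 of 35, 2, 2515) and anti-PD-L1 against mIgG1 (35 of 100, 2, 4588). In these 3 comparisons at least 1 other split called far more genes than the real split. The same holds for responder against intrinsic resistant tumours at day 14 (highest other 1668, real 0). This may point to a structure of the samples other than the groups compared. What that structure is was not tested. Where the real count was 0 every split gives as many, so the splits say nothing about chance. This applies to responder against intrinsic resistant blood at day 7 (100 of 100; highest other 59) and day 14 (100 of 100; 0), their change from day 7 to 14 (40 of 40; 0), and the differences of day 21 minus day 14 between these classes (40 of 40; 0; with mouse as a replicate block the real 37 was above the highest other of 10) and between the antibodies (40 of 40; 1). It applies in tumours to responder against intrinsic resistant mice at day 7 (35 of 35; 0) and day 14 (35 of 35; 1668), and to the change between the antibodies (100 of 100; 152) and between the classes (35 of 35; 46). The splits are too few for a share under 0.05 for responder against intrinsic resistant blood at day 28 (1 of 10; real 6123, highest other 0), day 35 against day 1 (1 of 4; 34, 0) and mIgG1 tumours of day 14 against day 7 (1 of 8; 4018, 1186).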

How the results depend on the processing

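The rRNA-related alternatives, the one without libraries of few detected genes, both of these joined with mouse as a replicate block (anti-PD-L1 tumours alone) and the comparisons of day 21 minus day 14 were added after the data were seen. Leaving aside single mice, 176 of 229 counts of called genes were within 1.5 times the reported count, and 2551 of 2958 results of named genes kept direction and side of the threshold (6 gained a call, 4 reversed and the rest lost one), as did 690 of 701 list medians. The largest rises and falls were named only with the same sign in both cohorts, so a cohort alone could not reverse them. The list medians cover only lists named in the text, tested at the preset correlation. These shares therefore do not describe all genes or lists. A comparison without called genes in both fits was scored as within 1.5 times. A preset gene uncalled in both, with the same direction, was scored as kept. The shares thus also hold agreement without any call. The 24 counts with haemoglobin genes left out and the 24 with rRNA-related genes left out were all within 1.5 times. Cohort alternatives apply where both cohorts hold the comparison, the one without few-gene libraries where the fit holds such a library, and blood day 7 against day 1 had no mice left out in turn. No scaling moved the median of all genes by over 0.1 (-0.097 to 0.075). For every count and value that moved, the cause was not tested.

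DESeq2 called 1303 genes in blood day 7 against day 1, 178 in the change between the antibodies, 862 in the antibodies at day 14, 0 in responder against intrinsic resistant blood at day 1 and 66 at day 14, 15 and 502 in the differences of day 21 minus day 14 (classes, antibodies), 329 in day 35 against day 1, and in day 14 tumours 27 for responder against intrinsic resistant, 1119 for acquired resistant against responder and 50 for the antibodies. DESeq2 size factors gave 10 for acquired resistant against responder tumours. Cohort 1 alone gave 246 and 1978 for day 14 against day 7 (mIgG1, anti-PD-L1), 0 for their difference, 1 and 18 for the antibodies at days 14 and 21, 0 and 1102 for responder against intrinsic resistant blood at days 1 and 21, and 103 for acquired resistant against responder. Cohort 2 alone gave 215 for day 7 against day 1, 672 for mIgG1 day 14 against day 7, 490 for the difference, 0 and 1764 for responder against intrinsic resistant at days 1 and 21, 262 for acquired resistant against responder and 203 for the antibodies at day 21 minus day 14. With mouse as a replicate block 697 were called in mIgG1 day 14 against day 7, 16 in the difference and 37 in the classes at day 21 minus day 14.

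Without libraries of few detected genes the counts were 1823 (mIgG1 day 14 against day 7), 199 (antibodies at day 14), 0 (classes at day 1), 122 (day 35), and in day 14 tumours 1 (responder against intrinsic resistant), 0 (acquired resistant against responder) and 0 (antibodies). With the rRNA-related share as a covariate they were 23 (change between antibodies), 125 and 476 (antibodies at days 14 and 21), 0 and 964 (responder against intrinsic resistant at days 1 and 21), 4 (day 35) and 0 (antibodies in tumours). Without libraries ending in R they were 128 (change between antibodies), 0 (classes at day 1) and 0 (acquired resistant against responder tumours), and with no filter 296 (antibodies at day 14), 0 and 2 (classes at days 1 and 14), 64 (day 35) and 12 (acquired resistant against responder tumours). Of 575 list tests 258 were called with the preset correlation and 16 with the estimated one. Gained with DESeq2 were Cd8a, Gzmb and Pdcd1 in acquired resistant against responder tumours (-4.18, -3.50 and -4.77), Cd8a in responder against intrinsic resistant tumours at day 14 (3.46) and Pdcd1 in day 35 against day 1 (2.78, and 2.74 without libraries of few detected genes). Reversed were Cd274 in responder against intrinsic resistant blood at day 14 in cohort 2 (-0.46, cohort 1 0.86), and Gzmb between the antibodies in day 14 tumours without libraries of few detected genes (-0.23) and without those ending in R (-0.62). Also reversed were Hbb-bs in blood day 7 against day 1 with DESeq2 (-0.14), the T cell list in the change between antibodies in cohort 1 (0.15), the erythroid list in mIgG1 day 14 against day 7 in cohort 2 (-0.0596) and the interferon gamma list in responder against intrinsic resistant blood at day 21 in cohort 1 (0.0939).

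Leaving out each mouse in turn gave, lowest to highest, 436 to 1412 and 3814 to 5483 for blood day 14 against day 7 (mIgG1, anti-PD-L1), 12 to 100 for their difference, 0 to 0 for the change between classes, 188 to 750 and 832 to 1859 for the antibodies at days 14 and 21, and 0 to 1, 0 to 0, 0 to 3, 3000 to 3941 and 4111 to 6028 for responder against intrinsic resistant blood at days 1, 7, 14, 21 and 28. It gave 611 to 1297 for acquired resistant against responder blood, 0 to 17 for day 35 against day 1, 0 to 0 and 0 to 650 for day 21 minus day 14 (classes, antibodies). In tumours it gave 0 to 0 for the classes at days 7 and 14, 0 to 955 for acquired resistant against responder, 0 to 4 for the antibodies at day 14, 1839 to 4893 and 4508 to 6924 for day 14 against day 7 (mIgG1, anti-PD-L1) and 0 to 0 for both differences of change. With a mouse left out Cd274 in responder against intrinsic resistant blood at day 14 ran from -0.0073 to 0.31, and Gzmb between the antibodies in day 14 tumours from -0.29 to 0.85. Of named gene results 3528 of 3947 were the same with a mouse left out.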

Other observations

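The tests of list scores here were all chosen after the values were seen. Over the 22 comparisons of blood and tumours, the MHC class II, macrophage, hypoxia and glycolysis, and mitochondrially encoded lists had medians from -1.58 to 1.70, -0.31 to 0.46, -0.72 to 1.03 and -1.25 to 1.62. At the preset correlation MHC class II was called up in 9 and down in 3 of them, macrophage in 1 and 1, hypoxia and glycolysis in 5 and 7, and mitochondrially encoded in 5 and 6; none was called with an estimated correlation.

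A hypothesis is that the lower neutrophil signal of responder blood begins before day 21. The mean log2 CPM over the mature neutrophil list per mouse was compared between responder and intrinsic resistant mice with exact permutation tests within cohorts, adjusted over 8 tests. The difference was -0.16 at day 1 (adjusted p = 0.555), -0.37 at day 7 (0.194), -0.71 at day 14 (0.00571) and -1.49 at day 21 (0.00571). The unadjusted exact p of the last pair, 0.00143, is the smallest that the 700 splits can give. At day 14 the means over all mice were 6.62 (SD 0.43, n = 7) and 7.38 (SD 0.45, n = 6). Each tested difference is the mean of the differences within the 2 cohorts (-0.73 and -0.69 at day 14), so it is not the difference of these means. The neutrophil signal in blood may therefore separate these classes 7 days after treatment began, in data that also raised the hypothesis. At day 14 edgeR called 0 genes between them, and the list test was not called with an estimated correlation.

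For cytotoxic and NK genes the same tests gave -0.48 at day 1, against the direction of the hypothesis that responders are higher (adjusted p = 0.286), 0.31 at day 7 (0.240), 0.52 at day 14 (0.169) and 0.77 at day 21 (0.00762).

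Another hypothesis is that T cell and cytotoxic genes in day 14 tumours are higher in responders. Exact permutation tests on list scores per mouse, adjusted over 6 tests, left it open. For T cell genes the difference was -2.70 for acquired resistant minus responder mice (adjusted p = 0.171), 1.62 for responder minus intrinsic resistant (0.240) and -1.08 for acquired minus intrinsic resistant (0.240). For cytotoxic and NK genes these were -2.22 (0.171), 0.75 (0.486) and -1.47 (0.240). Of the 4 responder aspirates, those of M391 and M401 had few detected genes. Without libraries of few detected genes the median fold change of the T cell list fell from 1.88 to 0.38 for responder against intrinsic resistant mice, and the call at the preset correlation was lost (adjusted p = 0.116). For acquired resistant against responder mice it went from -3.28 to -1.61 and for cytotoxic and NK genes from -2.87 to -1.35. In all libraries none of these 3 was called with an estimated correlation (adjusted p = 0.322, 0.213 and 0.230). With 3 and 4 mice, 35 splits give an exact p of at least 0.0286, and 3 against 3 at least 0.1.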
